A study of Mus musculus with 6 samples.

How the data were processed

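Total RNA from the RPE, choroid and sclera of mice aged 12 months, in 3 samples of heterozygous 5XFAD animals and 3 of wild-type littermates, was labelled with biotin and hybridised to Affymetrix whole-transcript mouse arrays, 1 array per sample, per the labels. Groups and replicate numbers were taken from the sample titles. The deposited values are normalized log2 intensities per probe set, made with Affymetrix Expression Console 1.1 and RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes arrays and summarises the probes of a probe set on the log2 scale. Filters, masking and any pooling of animals are not given in the sources used here. The deposited log2 table holds 33793 probe sets, and its per-array medians (5.59 to 5.71) were close but not identical, so values were used as deposited. No detection calls were used, and background compresses the fold changes of dim genes.

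Probe sets were named through a platform annotation table: 23521 had 1 gene symbol, 1814 had several and 8458 had none there. No gene was named from a probe set with several symbols. Entrez identifiers of 23328 probe sets matched a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols changed. That table was used only for names and for which genes neighbour each other, since the files give no coordinates or build. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all 6 arrays was kept, which left 22180 genes.

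The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate, 4 residual and 5.23 prior degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A looser count took an unadjusted p under 0.05 with a fold of at least 1.5. A set of 46 gene lists, for cell types that the dissection can hold and for pathways of the RPE, amyloid, ageing and macular degeneration, was fixed, and the 44 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists. Lists were also tested with camera at an estimated correlation and with fry, and each gene's p was adjusted over the list alone. A list mean per array is the mean of its genes, compared by an exact two-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1. The design, tests, lists, alternatives and the rule for named genes were set before the data were examined.

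Genes were named by this rule: the transgene-related genes, sex chromosome markers, in each direction the 10 genes of largest absolute log2 difference past the adjusted threshold whose groups did not overlap, and the 2 to 4 members of each list with the smallest unadjusted p. Where a direction had fewer than 10, it was filled with non-overlapping genes at an unadjusted p under 0.01, given as not passing. Predicted genes, olfactory and vomeronasal receptors and small RNAs were passed over in naming (51 in all). Names outside the rule were chosen after their values were seen: Krt6b, the surface epithelium members Krt14, Muc4, Pax6, Krt19, Krt12, Aldh3a1, Dsp and Perp, the RPE and visual cycle members Sulf1, Slc26a7, Otx2, Ttr, Stra6 and Rpe65, and genes given in the closing section with their neighbours or in its further list of epithelial genes.

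The steps were tested on simulated data with the real genes and 200 changed genes in each of 20 simulations. Among 22180 genes, limma recovered 12.3% of genes changed by 0.5 on the log2 scale, 89.0% of those changed by 1 and 99.5% of those changed by 2, with a mean of 6.55 false calls. The Benjamini-Hochberg cutoff on p loosens as more genes pass, and in the real data only 5 passed. Recovery there would be lower than with 200 changed genes, and these rates and false calls do not describe the real comparison. A list shifted by -0.3 was recovered in 100% of simulations, with a mean of 0.05 false lists, in data simulated without correlation between genes.

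Alternatives were the replicate number as a block, filters on the dimmest 30% or 50% of genes, another quantile normalization, median centring, a trended and robust prior, array weights, the mean of all probe sets of a gene, every probe set tested on its own, the rod or skeletal muscle list mean as a covariate, each array left out in turn, other fold thresholds, and for lists the estimated correlation, fry, ranks and lists without shared members.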

Results

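Gene expression was measured in the complex of retinal pigment epithelium (RPE), choroid and sclera of mice aged 12 months. The RPE is the pigmented cell layer that supports the photoreceptors, the choroid is the vascular layer behind it, and the sclera is the fibrous outer coat of the eye. The 3 samples of the first group came from heterozygous 5XFAD mice, a line that carries transgenes with familial Alzheimer's disease mutations, among them human amyloid precursor protein. The 3 samples of the second group came from wild-type littermates. The series title ties the animals to a pathology resembling dry age-related macular degeneration, and the comparison asks which transcripts of the outer eye wall differ between aged transgenic and wild-type mice. Each sample was hybridised to 1 array, and the number of arrays limits the precision. The labels do not state that each sample came from a separate animal, so that p-values measure the spread between these samples, which may be partly technical. Median log2 intensity per array lay between 5.59 (wild type replicate 2) and 5.71 (wild type replicate 3). Correlations between arrays over all probe sets ran from 0.981 to 0.990 within groups and from 0.983 to 0.990 between groups, with means of 0.9868 and 0.9865. Wild type replicate 2 had the lowest mean correlation with the other arrays (0.984).

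The amyloid precursor protein gene and the gene whose promoter drives the 5XFAD transgenes were measured first. App signal was 11.85 ± 0.12 in 5XFAD and 11.77 ± 0.22 in wild type (log2 intensity, mean ± SD, n = 3 per group, as for all levels given here). The difference of 0.09 ± 0.13 (log2, ± SE) lay within the replicate spread (limma, Benjamini-Hochberg adjusted p = 0.96). Thy1 signal was 7.64 ± 0.14 against 7.36 ± 0.18, a difference of 0.28 ± 0.12 that did not pass the threshold (limma, Benjamini-Hochberg adjusted p = 0.80). Mouse probes need not bind the human transcripts, so these values check the genotype labels only in part. The Y-linked genes Uty, Kdm5d and Eif2s3y lay between 6.48 and 7.99 in all 6 arrays and Xist between 3.30 and 3.89, with no difference between the groups past the threshold (limma, lowest Benjamini-Hochberg adjusted p = 0.95 for Xist).

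Keratin genes of stratified epithelium made up 4 of the 5 genes that rose in 5XFAD tissue past the adjusted threshold. Krt15, a keratin of basal epithelial cells, was 11.7-fold higher, at 8.43 ± 0.85 against 4.87 ± 0.21. Krt4 and Krt13, a keratin pair of mucosal epithelia such as the conjunctiva, were 9.26-fold and 2.92-fold higher, at 7.71 ± 0.51 against 4.50 ± 0.14 and 6.88 ± 0.33 against 5.33 ± 0.14. Krt6a, a keratin of activated and stratified epithelium, was 3.63-fold higher, at 5.75 ± 0.37 against 3.89 ± 0.06. The only other gene that passed was Gsto1, a glutathione transferase of the omega class, which was 3.87-fold higher, at 9.46 ± 0.25 against 7.51 ± 0.12. For each of these 5 genes all 3 5XFAD arrays lay above all 3 wild-type arrays.

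With limma, Benjamini-Hochberg adjusted p-values were 0.0018 for Krt4, 0.0018 for Gsto1, 0.0093 for Krt6a, 0.013 for Krt15 and 0.021 for Krt13. The log2 differences were 3.21 ± 0.22, 1.95 ± 0.14, 1.86 ± 0.17, 3.55 ± 0.34 and 1.55 ± 0.16 in the same order (± SE). Of 22180 genes tested, these 5 passed, all higher in 5XFAD, and 0 genes passed as lower. At an unadjusted p under 0.05, limma gave 1392 genes (640 higher and 752 lower), where 1109 would come by chance. When arrays were centred on their medians the adjusted count was 7 higher and 1 lower, and after another quantile normalization it was 6 higher and 1 lower. A fold of at least 1.5 at an unadjusted p under 0.05 was met by 159 genes, 106 higher and 53 lower in 5XFAD. The 3 values per group did not overlap in 2516 genes (11.3%), where chance gives 10%. In wild type, Krt6a lay at percentile 17.8 of all probe sets, Krt4 at 28.0, Krt15 at 34.9 and Krt13 at 43.5, where background compresses fold changes. Krt6a has a close paralog, Krt6b, whose signal was 2.49-fold higher in 5XFAD without passing (limma, Benjamini-Hochberg adjusted p = 0.087), and the 2 signals may be shared in part. Krt4 and Gsto1 stayed past the threshold with each array left out in turn, whereas without wild type replicate 3 limma gave Benjamini-Hochberg adjusted p-values of 0.091 for Krt15, 0.066 for Krt6a and 0.091 for Krt13. Krt13 also lost its call without 5XFAD replicate 3 (0.074) and without wild type replicate 1 (0.11), with the skeletal muscle list as a covariate (0.13) and with every probe set tested on its own (0.093, limma, Benjamini-Hochberg adjusted p). Krt15 lost its call with a trended and robust prior (0.090) and with every probe set tested on its own (0.070, limma, Benjamini-Hochberg adjusted p).

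**Figure D1:**
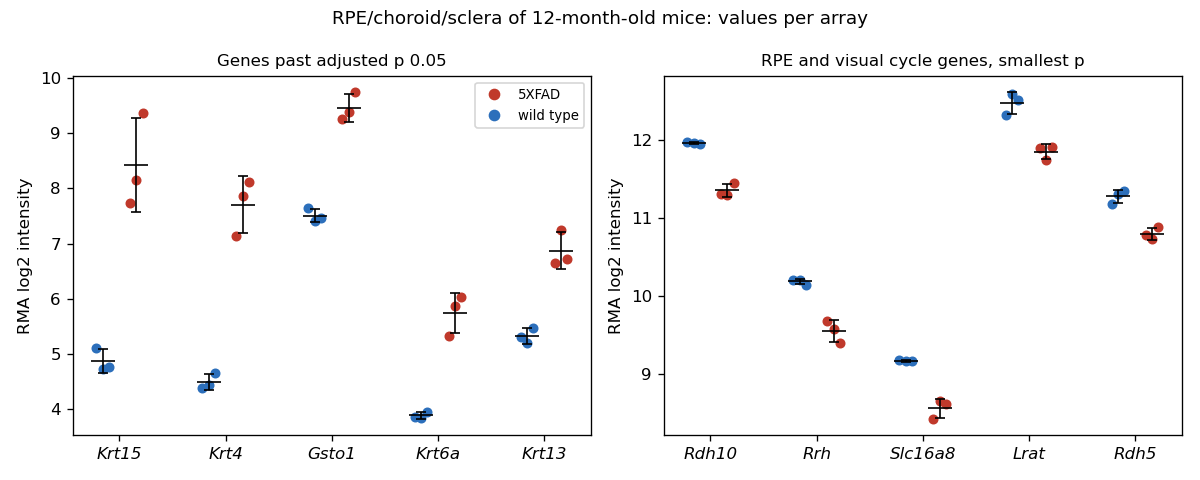
RMA log2 intensity per array (points), with group means and SDs (bars, n = 3), for wild-type (blue) and 5XFAD (red) tissue. Left, the 5 genes past an adjusted p of 0.05, each with all 5XFAD arrays above all wild-type arrays. Right, 5 genes of the RPE and the visual cycle, picked for the smallest unadjusted p in their lists. None of the genes on the right passed the adjusted threshold, and their 5XFAD arrays all lie below the wild-type arrays.

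Other large differences did not pass the adjusted threshold. Aqp3, a water and glycerol channel of epithelia, was 3.11-fold higher (limma, Benjamini-Hochberg adjusted p = 0.054), and Scel, which encodes the epithelial protein sciellin, was 3.07-fold higher (0.46). The immunoglobulin segment Igkv4-72 was 3.66-fold higher (0.090), the muscle myosin gene Myh1 3.91-fold (0.44) and Crhbp, encoding the binding protein of corticotropin-releasing hormone, 2.69-fold (0.59). Among the 10 genes named as lower, those of most negative difference with non-overlapping groups and an unadjusted p under 0.01 once predicted genes, receptors and small RNAs were passed over, Cdhr1, a photoreceptor cadherin, differed by -0.86 ± 0.10 (limma, Benjamini-Hochberg adjusted p = 0.0503). Lrit2 differed by -0.93 ± 0.12 (0.054), Dusp6, a phosphatase of ERK, by -0.92 ± 0.13 (0.087), Slco1c1, a thyroid hormone transporter, by -0.92 ± 0.17 (0.17) and Trhde, which degrades thyrotropin-releasing hormone, by -0.83 ± 0.12 (0.11). Log2 differences were -0.89 for Sema3c, -0.79 for the glutamate transporter gene Slc1a1, -0.78 for the serotonin receptor gene Htr3a, -0.76 for the histone gene H4c9 and -0.76 for the cone phosphodiesterase gene Pde6c. Their limma Benjamini-Hochberg adjusted p-values ran from 0.15 for Slc1a1 to 0.44 for H4c9. Cdhr1 passed with limma after the dimmest 30% of genes were left out (Benjamini-Hochberg adjusted p = 0.043), as did Lrit2 and Aqp3 (both 0.046). Without wild type replicate 2, Scel (0.028) and Crhbp (0.037) passed, as did Igkv4-72 without 5XFAD replicate 1 (0.026, limma, Benjamini-Hochberg adjusted p).

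The list of cornea, conjunctiva and surface epithelium genes, 1 of 44 lists tested, rose in 5XFAD. Of its 16 measured genes, 4 passed over all genes and 8 when adjusted over the list alone, all higher. Beside the 4 keratins named above these were Krt14 (6.12 ± 0.30 against 5.02 ± 0.31), the mucin gene Muc4 (log2 difference 1.24 ± 0.21), the eye transcription factor gene Pax6 (1.07 ± 0.29) and Krt19 (0.37 ± 0.13). The remaining 8 did not pass, among them the corneal genes Krt12 (0.40 ± 0.30) and Aldh3a1 (-0.07 ± 0.21) and the junction and barrier genes Dsp (-0.19 ± 0.18) and Perp (-0.01 ± 0.11). The median log2 difference was 0.38, and the list mean was 6.80 ± 0.23 in 5XFAD and 5.92 ± 0.02 in wild type, with all arrays apart (limma camera, Benjamini-Hochberg adjusted p = 3.3e-12). The adjusted p was 0.24 with an estimated correlation. The median was 0.59 without 5XFAD replicate 1 and 0.21 without 5XFAD replicate 3, and 0.25 and 0.07 without the dimmest 30% and 50% of genes, with the call kept in each case.

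Genes that define the RPE fell in 5XFAD tissue as a list. All 24 were measured, 22 had a negative difference, and the median was -0.38, a 0.768-fold level. The list mean was 9.95 ± 0.09 in 5XFAD and 10.26 ± 0.09 in wild type, and all 3 5XFAD arrays lay below all 3 wild-type arrays (limma camera, Benjamini-Hochberg adjusted p = 6.9e-14). The adjusted p was 0.47 with an estimated correlation. In the same arrays the mean of the surface epithelium list was higher by 0.89 and that of the skeletal muscle list by 0.49. Over all genes 0 members passed (limma), while 15 were under an unadjusted p of 0.05 and 15 passed when adjusted over the list alone, 14 of them lower. The lower members included the retinol dehydrogenase gene Rdh10 (-0.60 ± 0.10), the opsin gene Rrh (-0.64 ± 0.11), the lactate transporter gene Slc16a8 (-0.61 ± 0.10) and Lrat (-0.62 ± 0.11), which encodes the enzyme that esterifies retinol. Sulf1 (-0.55 ± 0.11), Slc26a7 (-0.48 ± 0.11), Otx2 (-0.40 ± 0.13), a transcription factor gene of the RPE, and Ttr (-0.25 ± 0.09), encoding the retinol carrier transthyretin, were also among them. The single higher member was the tight junction gene Cldn19 (0.66 ± 0.17), which has 2 probe sets and ran from 0.33 to 0.83 under the alternatives.

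The visual cycle, the pathway that regenerates the chromophore of photoreceptor pigments, also fell as a list. Of 16 measured genes 14 had a negative difference, with a median of -0.29, and the list mean was 9.11 ± 0.03 against 9.41 ± 0.03 with all arrays apart (limma camera, Benjamini-Hochberg adjusted p = 3.0e-09). The adjusted p was 0.19 with an estimated correlation. In limma 0 members passed over all genes, 7 were under an unadjusted p of 0.05, and 7 were lower when adjusted over the list alone. These were Rdh10, Rrh, Lrat, Rdh5 (-0.48 ± 0.10), the retinol uptake receptor gene Stra6 (-0.45 ± 0.12), Rlbp1 (-0.54 ± 0.16), which encodes a retinaldehyde carrier, and the isomerase gene Rpe65 (-0.33 ± 0.11). The list shares 8 measured members with the RPE list, and without members held by another list its median was -0.11 (limma camera, Benjamini-Hochberg adjusted p = 0.23).

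Other functions of the RPE showed mixed differences, and their lists did not pass camera, although melanin passed under 5 of 20 alternatives and ion transport under 4. Single arrays decided some of these calls: melanin passed without 5XFAD replicate 3, wild type replicate 1 or wild type replicate 2, and ion transport without wild type replicate 1 or 3. In the ion transport list (limma camera, Benjamini-Hochberg adjusted p = 0.095) 4 of 19 genes were lower when adjusted over the list alone and 0 over all genes, with 6 lower at an unadjusted p under 0.05. They were Slc16a8, the lactate transporter gene Slc16a1 (-0.63 ± 0.11), the carbonic anhydrase gene Car12 (-0.54 ± 0.14) and the chloride channel gene Clcn2 (-0.51 ± 0.14). The melanin list had a median of 0.06 (limma camera, Benjamini-Hochberg adjusted p = 0.061), with Trpm1 at 0.62 ± 0.21, Rab38 at 0.31 ± 0.11, Mlana at 0.25 ± 0.11 and Pmel at 0.24 ± 0.12. In the phagocytosis list (limma camera, Benjamini-Hochberg adjusted p = 0.85) 0 members passed over all genes and 3 were under an unadjusted p of 0.05. When adjusted over the list alone, the integrin gene Itgav (-0.75 ± 0.12) was lower and Mfge8 (0.41 ± 0.11), which encodes its bridging ligand, higher. Itgav has 2 probe sets, and its difference ran from -0.84 to -0.37 under the alternatives. In the list of tight and adherens junctions (0.93) Cldn1 (-0.65 ± 0.14) was lower and Cldn19 higher when adjusted over the list alone. There 0 members passed over all genes and 4 were under an unadjusted p of 0.05. The median of both lists was positive and the mean negative, at 0.005 and -0.005 for phagocytosis and 0.008 and -0.016 for junctions, while camera pointed upward for phagocytosis and downward for junctions.

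Muscle, immune and connective tissue lists gave the other calls, and all of these were lost with an estimated correlation. The skeletal muscle list rose by a median of 0.42 (limma camera, Benjamini-Hochberg adjusted p = 2.3e-06; adjusted p = 0.68 with an estimated correlation). Its mean was 6.44 ± 0.46 against 5.94 ± 0.55 with overlapping arrays, and 0 of 30 genes passed over all genes or adjusted over the list alone, with 5 higher at an unadjusted p under 0.05 in limma. Acta1 (1.13 ± 0.47), Mybpc1 (0.97 ± 0.38) and Myh3 (0.96 ± 0.26) were among the members of smallest p. The muscle median kept its call but was 0.25, 0.26 and 0.27 without 5XFAD replicate 1, wild type replicate 1 and wild type replicate 2, and 0.65 and 0.71 without 5XFAD replicate 3 and wild type replicate 3. The macrophage and microglia list rose by a median of 0.14, with 22 of 25 genes positive (limma camera, Benjamini-Hochberg adjusted p = 9.9e-05; adjusted p = 0.68 with an estimated correlation). Fcer1g (0.51 ± 0.16) and Tyrobp (0.29 ± 0.12), adaptor genes of myeloid receptors, Itgam (0.25 ± 0.10) and Gpnmb (0.24 ± 0.10) had the smallest p. With the skeletal muscle list mean as a covariate the macrophage call was lost (median 0.05; limma camera, Benjamini-Hochberg adjusted p = 0.075), and 5XFAD replicate 1 had the highest mean of both lists. The T cell and NK cell list fell by a median of 0.22, with all arrays apart (limma camera, Benjamini-Hochberg adjusted p = 0.0081; adjusted p = 0.68 with an estimated correlation), with Cd3g at -0.40 ± 0.16 and Cd8a at -0.28 ± 0.11. Its genes were dim, with a list mean of 5.44 ± 0.12 against 5.59 ± 0.01, and the call was lost without the dimmest 30% of genes (limma camera, Benjamini-Hochberg adjusted p = 0.062). The fibroblast and sclera list rose by a median of 0.18 (limma camera, Benjamini-Hochberg adjusted p = 0.0082; adjusted p = 0.68 with an estimated correlation), with the matrix genes Aspn at 0.49 ± 0.14 and Prelp at 0.30 ± 0.11 and with Col1a2 at -0.22 ± 0.11. The list of epithelial to mesenchymal transition rose by a median of 0.09 (limma camera, Benjamini-Hochberg adjusted p = 0.015; adjusted p = 0.68 with an estimated correlation), with Fn1 at 0.34 ± 0.11. Without members held by another list its call was lost (limma camera, Benjamini-Hochberg adjusted p = 0.16). The arrays of the 2 groups overlapped in the means of the macrophage, fibroblast and transition lists (exact two-sided permutation p = 0.4, 0.3 and 0.2). In these immune and connective tissue lists 0 genes passed over all genes or adjusted over the list alone, and in limma 4, 4, 3 and 5 were under an unadjusted p of 0.05. Without 5XFAD replicate 1 the macrophage, fibroblast and transition lists no longer passed (limma camera, Benjamini-Hochberg adjusted p = 0.15, 0.14 and 0.15). Their medians were then 0.06, 0.10 and 0.06, while without 5XFAD replicate 3 the macrophage and fibroblast medians were 0.22 and 0.27. The fibroblast list was also lost without 5XFAD replicate 2 (0.16; median 0.10), the fibroblast and transition lists without wild type replicate 3 (both 0.21; medians 0.04 and 0.08), and the T cell list without 5XFAD replicate 3 (0.14).

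**Figure D2:**
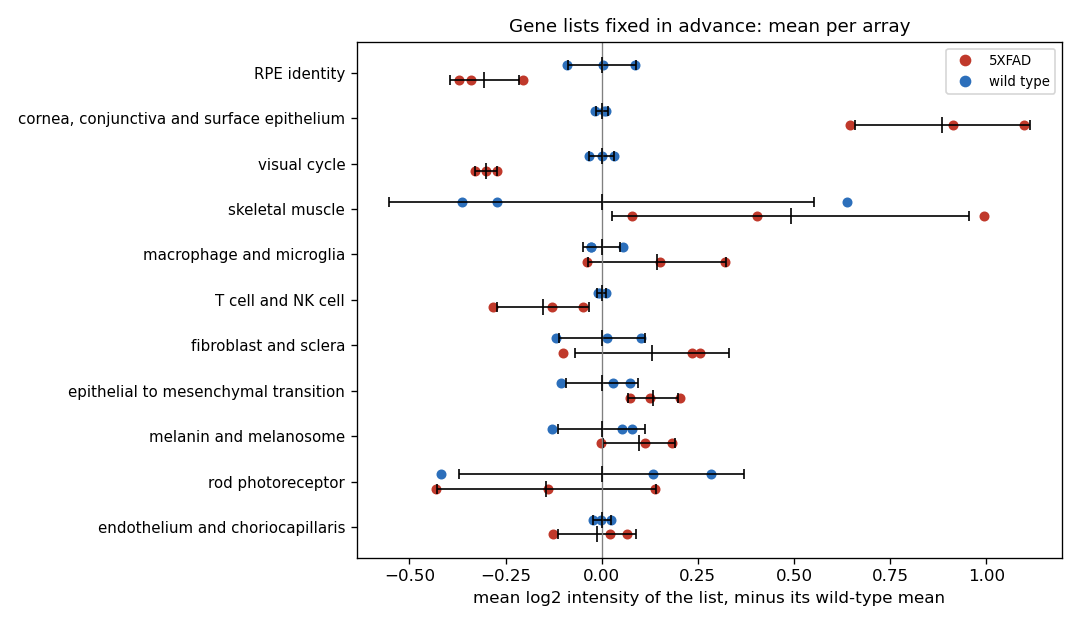
Mean log2 intensity of each gene list per array, minus the wild-type mean of that list, for wild-type (blue) and 5XFAD (red) tissue; black bars give group means and SDs (n = 3). The first 8 lists passed camera and the last 3 did not; the arrays of the 2 groups are apart for RPE identity, surface epithelium, the visual cycle and T and NK cells, and overlap for skeletal muscle.

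In total 8 of 44 lists passed camera with its preset correlation of 0.01, 5 higher and 3 lower. Of the 10 splits of the 6 arrays into 3 and 3, 6 gave at least 8 lists, the real one included (highest other 13). The count of lists therefore does not set the genotype apart from other groupings of these arrays. With an estimated correlation 0 passed (3 at an unadjusted p under 0.05), and with limma's fry, which tests whether the genes of a list move one way on balance, the visual cycle alone passed (Benjamini-Hochberg adjusted p = 0.018). In the mixed test of limma's fry, which asks for change in either direction, 9 lists passed (lowest Benjamini-Hochberg adjusted p = 0.0060). They were the RPE, surface epithelium, visual cycle and T cell lists and, among lists that did not pass camera, tight and adherens junctions (0.0060), ciliary body and iris (0.0067), ion transport (0.013), macular degeneration risk loci (0.014) and Muller glia and astrocytes (0.025). For the RPE, surface epithelium and visual cycle lists the exact two-sided permutation p of the list mean was 0.1. That is the smallest value that 3 against 3 arrays allow. It was also 0.1 for the T cell list and, among lists that did not pass camera, for adipocytes and macular degeneration risk loci. For skeletal muscle it was 0.3.

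Lists drawn from amyloid biology and macular degeneration did not pass camera as planned. In the list of amyloid precursor processing and clearance (limma camera, Benjamini-Hochberg adjusted p = 0.61; median 0.003, mean -0.040, test downward) 1 of 25 genes was lower when adjusted over the list alone and 0 over all genes, with 3 lower at an unadjusted p under 0.05. That gene, the endocytic receptor gene Lrp2, differed by -0.61 ± 0.14, the sorting receptor gene Sorl1 by -0.41 ± 0.12 and Aplp1 by -0.49 ± 0.14. In the list of genes at macular degeneration risk loci (limma camera, Benjamini-Hochberg adjusted p = 0.095), 2 of 29 genes were lower when adjusted over the list alone, Slc16a8 and Rdh5, and 0 over all genes, with 5 lower at an unadjusted p under 0.05. The list passed the mixed test of limma's fry (Benjamini-Hochberg adjusted p = 0.014) and camera without wild type replicate 1 or with the rod list mean as a covariate. The collagen gene Col8a1, also a member, differed by -0.51 ± 0.14. Complement genes had a median of 0.09 (limma camera, Benjamini-Hochberg adjusted p = 0.24), with 0 of 27 under an unadjusted p of 0.05. Bruch's membrane matrix genes had a median of 0.04 (0.095), interferon response genes -0.12 (0.16), lysosome and autophagy genes 0.006 (0.21) and oxidative phosphorylation genes 0.03 (0.24; limma camera, Benjamini-Hochberg adjusted p in parentheses). Bruch's membrane genes passed without 5XFAD replicate 2 or wild type replicate 2, with the skeletal muscle covariate and without shared members. Interferon genes passed without wild type replicate 1 or 3 and with the rod covariate, complement and lysosome genes without 5XFAD replicate 3, and oxidative phosphorylation genes without 5XFAD replicate 3 or wild type replicate 2. In the oxidative stress list (0.93, with a median of -0.05, a mean of 0.04 and a downward test) the cystine transporter gene Slc7a11 differed by 0.91 ± 0.25. This difference ran from 0.44 to 1.19 under the alternatives. Among cytokine genes (0.85) Ccl3 was higher by 0.62 ± 0.13 when adjusted over the list alone. So was Pgf, a growth factor gene of the VEGF family, by 0.49 ± 0.11 in the angiogenesis list (0.81). Over all genes 0 members of either list passed. At an unadjusted p under 0.05 in limma, 2 cytokine genes were higher and 2 lower, and 1 angiogenesis gene was higher. The cytokine list had a median of 8.9e-05 and a mean of -0.006 and the angiogenesis list a median of -0.02 and a mean of 0.007, and camera pointed upward for both.

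Markers of neighbouring tissues were compared as a measure of what each sample held. Rod photoreceptor genes were at 6.44 ± 0.28 in 5XFAD and 6.59 ± 0.37 in wild type (limma camera, Benjamini-Hochberg adjusted p = 0.095), and cone genes at 5.21 ± 0.09 and 5.32 ± 0.04 (0.24). The rod list passed without 5XFAD replicate 1 or wild type replicate 2, the pericyte list without 5XFAD replicate 3 and the ciliary body list without wild type replicate 2. Endothelial genes were at 8.12 ± 0.10 and 8.13 ± 0.02 (0.92), with 0 of 20 members under an unadjusted p of 0.05 in limma. Pericyte and smooth muscle genes had a median log2 difference of 0.12 (0.095), adipocyte genes 0.11 (0.095), lens crystallin genes -0.08 (0.095), Schwann cell genes -0.03 (0.30) and lacrimal and Harderian gland genes -0.07 (0.30; limma camera, Benjamini-Hochberg adjusted p in parentheses). Ciliary body and iris genes had a median of 0.22 (limma camera, Benjamini-Hochberg adjusted p = 0.095). In that list Zic2 (0.94 ± 0.14) and Zic1 (1.28 ± 0.36) were higher and Rdh10 lower when adjusted over the list alone, with 0 past over all genes and 4 under an unadjusted p of 0.05. Zic2 passed over all genes only without wild type replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.026).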

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

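The tests of explanations given here were chosen after the keratins had passed their threshold and before the results of those tests were seen. Outside the genes with a single symbol, 1 probe set annotated to several symbols was higher in 5XFAD by 1.85 on the log2 scale (3.60-fold, 7.87 ± 0.28 against 6.02 ± 0.07, mean ± SD, n = 3 per group; limma over all 33793 probe sets, Benjamini-Hochberg adjusted p = 0.017). It drew attention because the comparisons above do not use such probe sets, and it is named for no gene here. Of the 8458 probe sets without a symbol, 0 passed in limma, and 407 were under an unadjusted p of 0.05.

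The 4 keratins passed as higher in 5XFAD, in a tissue for which the labels name no sorting, and their list of 16 surface epithelium genes, 12 positive and 4 negative, passed camera but not with an estimated correlation (limma, Benjamini-Hochberg adjusted p = 0.24). The rise of the list mean was not confined to 1 array. The lowest 5XFAD array lay 0.63 above the highest wild-type array, with a pooled SD within groups of 0.16. The 4 keratins belong to this list and each had all arrays apart. The gap therefore describes the rise and is not separate evidence on its cause. Ocular surface epithelium carried into the 5XFAD samples is a candidate explanation that the tables leave open. A second list of 33 epithelial genes, none held by another list, had a median log2 difference of 0.15 over 32 measured genes, at percentile 100 of 10000 random lists matched on mean expression (median of the random lists -0.01), although 0 of them passed in limma, 10 were higher and 1 was lower at an unadjusted p under 0.05, and of its 7 members above the median gene in wild type 3 were among those higher, Upk1b (7.06 against 6.39), Cd24a (9.29 against 8.93) and Aqp5 (6.89 against 6.56). A change of epithelial genes with the genotype would move both lists too, stays open and was not tested, and the random lists are not matched on correlation between genes; 6 of the 16 genes of the first list also lay above the median gene in wild type.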

How the results depend on the processing

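No alternative was added after the results were seen. App and Thy1 kept their direction and side of the threshold under all 17 alternatives each. Krt4 and Gsto1 passed limma under all 17 alternatives (Benjamini-Hochberg adjusted p 1.4e-04 to 0.026 and 0.0011 to 0.026), Krt15 and Krt6a each under 14 (0.0020 to 0.091 and 0.0012 to 0.066; Krt6a was not among the genes kept by the filters) and Krt13 under 11 (0.015 to 0.13). Cdhr1 passed under 7 of 17 (0.020 to 0.26), Aqp3 under 6 and Lrit2 under 3. The adjusted count of 5 genes became 8 without the dimmest 30% of genes, 8 with median centring, 9 with a trended and robust prior and 8 with array weights; it ran from 3 (without wild type replicate 3) to 19 (without wild type replicate 2) with 1 array left out. The count of 159 genes became 239 with the skeletal muscle list as a covariate, 566 at a fold of 1.3 and 36 at a fold of 2, which follows from the threshold, and ran from 163 to 273 (without wild type replicate 2) with 1 array left out, with 240 without 5XFAD replicate 3. The 8 lists became 0 with an estimated correlation and 1 with fry, and ran from 7 (without 5XFAD replicate 1) to 13 (without wild type replicate 2) with 1 array left out. The cause was not tested for the counts that moved without a change of threshold. With its own mean as a covariate the skeletal muscle list had a median of -0.027, as that covariate is built to do, and the macrophage list no longer passed (adjusted p = 0.075). Without members shared with other lists the visual cycle (adjusted p = 0.23) and transition lists (0.16) were lost. T and NK cells were also lost without the dimmest 30% of genes (adjusted p = 0.062) and had fewer than 5 genes left to test without the dimmest 50%, and the RPE and surface epithelium lists passed under 18 of 20 alternatives each, with medians from -0.50 to -0.30 and from 0.07 (without the dimmest 50% of genes) to 0.59. The skeletal muscle median reached 0.85 without the dimmest 50% of genes. Of the lists that did not pass, melanin passed under 5 of 20 alternatives, ion transport, Bruch's membrane, rods and ciliary body under 4 each, interferon response under 3, macular degeneration risk loci and oxidative phosphorylation under 2, and complement, lysosome, MHC and pericytes under 1. Genes with no call changed sign: Xist (-0.072) and Uty (-0.0066) with the skeletal muscle covariate, Uty between -0.076 and 0.13 and Kdm5d between -0.17 and 0.049 with 1 array left out. No pairing by replicate number was seen: deviations of same-numbered arrays correlated at -0.06, -0.05 and 0.13, and 2 of 6 arrays correlated best with their own number. So few arrays cannot exclude a pairing, and the labels state none. With the number as a block limma gave 6 genes (4 of the 5 among them, with Krt13 at an adjusted p of 0.0501), 183 genes and 10 lists. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The count of 5 genes was reached by 1 of 10 splits, the real one (highest other 0), the count of 159 also by 1 (highest other 128), and the count of 8 lists by 6, the real one included (highest other 13). The dim signal of the keratins in wild type limits the precision of their folds.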

Other observations

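The tests of why RPE genes were lower were chosen after the list results were seen; those on Gsto1 were chosen before their own results. Further lists, fixed in advance, did not pass camera as planned. In the list of Muller glia and astrocyte genes (limma camera, Benjamini-Hochberg adjusted p = 0.30), the glutamate transporter gene Slc1a3 (log2 difference 0.99 ± 0.26) and Dkk3 (0.51 ± 0.15) were higher and Rlbp1 lower when adjusted over the list alone, and 0 passed over all genes, with 4 under an unadjusted p of 0.05. The MHC class II genes H2-Ab1, H2-Aa and H2-Eb1, which present antigen on myeloid and B cells, differed by -0.62 ± 0.24, -0.47 ± 0.19 and -0.36 ± 0.14, and their list did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.30), except without 5XFAD replicate 1. Without 5XFAD replicate 3 these differences were -0.29, -0.23 and -0.24. The mast cell protease genes Tpsb2 (0.56 ± 0.14) and Cma1 (0.32 ± 0.12) and the antibody joining chain gene Jchain (0.70 ± 0.24) had positive differences in lists that did not pass either (0.23 and 0.82; limma camera, Benjamini-Hochberg adjusted p). Mpo, in the same mast cell and granulocyte list as Tpsb2 and Cma1, differed by -0.29 ± 0.11. The difference of Jchain ran from 0.34 to 0.88 under the alternatives. The B cell and plasma cell list of Jchain had a median of -0.02 and a mean of 0.09, and its test pointed upward. Immediate early genes, which respond to tissue handling, had a median of -0.07 (0.21), and circadian clock genes a median of -0.002 with a mean of 0.04 and an upward test (0.85; limma camera, Benjamini-Hochberg adjusted p in parentheses).

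Cdhr1 and Lrit2, with the lowest adjusted p among genes lower in 5XFAD, are direct neighbours in the GRCm38.p6 gene order. The next genes on the side of Lrit2 are Lrit1, at -0.24 ± 0.14, and the RPE opsin gene Rgr, at -0.23 ± 0.12. On the other side of Cdhr1 lies 2610528A11Rik, at 1.44 ± 0.27 (limma, Benjamini-Hochberg adjusted p = 0.20), followed by Ghitm at -0.08 ± 0.14.

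The RPE and visual cycle lists were lower in 5XFAD with camera's preset correlation, but not past the threshold with an estimated one (limma, Benjamini-Hochberg adjusted p = 0.47 and 0.19), and 0 of their members passed over all genes (15 and 7 under an unadjusted p of 0.05). Endothelial genes did not share the fall: their list shifted by 0.29 more than the RPE list, with a pooled SD of 0.08. Both shifts had been seen when this comparison was chosen, and carried-over tissue can hold vessels of its own. A dilution of RPE by other tissue therefore stays open. The other cell types were not all raised alike, since the surface epithelium list shifted by 0.90 more than the endothelium list, with a pooled SD of 0.20. The surface epithelium list was already known to rise, so this pair does not decide whether the share of RPE was lower. Other RPE function lists did not all fall with the RPE list. Mean log2 differences were 0.10 for melanin (13 genes positive and 4 negative), -0.005 for phagocytosis, -0.016 for junctions and -0.10 for ion transport. These were fixed as pathway lists and not as measures of cell share, so they do not decide the question. A lower share of RPE in samples that also held more surface epithelium stays open, as does a lower expression per RPE cell, and neither was tested. A difference between the genotypes is among the open explanations and was likewise not tested.

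Gsto1 was higher in each 5XFAD array than in each wild-type array, by 3.87-fold, while its neighbour Gsto2 differed by -0.09 ± 0.11. A chromosome segment of another strain around Gsto1 is a candidate explanation, to which the neighbouring genes gave no support. Of 91 genes within 5 Mb, 5 were under an unadjusted p of 0.05 in limma (5.49%), against 6.28% of all genes. That placed the share at percentile 35.0 on the chromosome. Such a segment need not hold other affected genes, and the strain is not given in the sources used here, so that this cannot be told apart from an effect of the genotype. Surface epithelium as the source of Gsto1 stays open too, since the ratio of Gsto1 excess to keratin excess varied 1.504-fold between the 3 5XFAD arrays, between the bounds set for and against it.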
